A study of Mus musculus with 42 samples.

How the data were processed

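RNA from 21 mouse mammary tumours was measured on 42 two-colour arrays printed with a library of long oligonucleotide probes, 2 arrays for each tumour. Per the labels, tissue was kept in a stabilising solution, total RNA was extracted with TRIzol, cDNA was labelled with Cy3 or Cy5, and each tumour was hybridised in a dye-swapped pair against a universal mouse reference RNA. The 2 arrays of a tumour were therefore treated as technical repeats. The deposited values are log2 ratios of one dye over the other, a scale read from the values, since the labels' protocol breaks off before the image processing. Background correction, normalization and which array of a pair carries which dye are not given in the sources used here. The deposited table had 22800 probes, 726515 values and 24.1% blank cells, with values from -9.87 to 12.69 below a repeated top value of 16.61, the log2 of 100000. These 15512 top values (2.14% of values) were treated as missing, on the reading that they stand for a denominator of 0, which the labels do not give and which was not tested. With them kept, a setting chosen after seeing the data, 1846 probes differed, and the adjusted p became 0.146 for Acta1, 0.344 for Tgfbr2 and 0.0659 for Cd74. Many values were exactly log2 of ratios of small whole numbers, which marks dim probes.

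Raw correlations between the 2 arrays of a tumour ran from -0.565 to 0.074 over probes, and 20 of 21 were below 0. This shows that deposited ratios had not been turned for the dye swap. Tumour 656, at 0.074, was the exception, so its 2 arrays did not agree over probes after turning. The arrays of each tumour were taken to be opposed, per the labels' dye swap, and their difference was computed per probe. Which of the pair had which orientation came from the sign of the tumour's loading on the first eigenvector of the correlations between these 21 differences, leaving 21 arrays in each orientation. After turning, the differences had a median correlation of 0.379 between tumours and a lowest of -0.035, with 1 pair of tumours below 0. The same orientation came from both random parts of the probes for 42 arrays. Arrays of a single orientation had a median correlation of 0.296 and a lowest of -0.239, so none fell under -0.3. Arrays of the second orientation were multiplied by -1, and the overall sign was set so that Myc was positive. What remains unknown is that overall sign, and with it the direction against the reference, together with the authors' centring. After turning, array medians ranged from -1 to 1.38 and medians of tumour means from -0.83 to 0.59. Tests used the deposited scale without centring, and levels of named genes were given after subtraction of the array's own median over all its measured probes.

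Probe names came from the platform annotation: 16874 probes had 1 gene symbol, 134 had several and 5792 had none, and 16196 were matched to a current gene entry through their gene identifier. A set of 232 Gapdh control spots was averaged to 1. A probe was tested where both arrays of at least 15 tumours had a value, which left 9407 probes, 7984 of them with 1 gene and 7629 genes in all. For list tests and list members the probes of a gene were averaged and p-values adjusted over genes, and for the most variable genes and those on a single side of the reference the probe was the unit.

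Differences between tumours were tested with limma, by a linear model with the tumour as a factor of 21 levels, empirical Bayes moderation and a moderated F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count asked for a range of tumour means of at least 2 on the log2 scale, which is 4-fold. All 210 pairwise contrasts were taken from the same fit with a log2 difference of at least 1. The variance share between tumours was the one-way intraclass correlation. The closest array was found by Pearson correlation and tested with 100000 random pairings. The gene lists were compared with 10000 random lists of the same size, matched on hybridisation error for variation and on the standard deviation of tumour means for joint movement, both one-sided, for lists with at least 5 measured genes, a minimum set when the measured members were known. List scores were means of standardised genes, related by Pearson and Spearman correlation with 100000 permutations, two-sided, or exact enumeration with fewer than 10 tumours. Components were found with mclust (1 to 3 components by BIC), and where a score had several, correlations were taken within components of at least 6 tumours. Where both scores of a pair had several, the components of the first were used. Slide run, of 9, 13 and 20 arrays, came from running numbers in the titles, and the labels do not say whether it is a batch of printing or hybridisation.

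The fixed lists were epithelial, mesenchymal, extracellular matrix, milk and secretory, basal and myoepithelial, hormone response and luminal, proliferation, Myc targets, macrophage, T and NK cell, B and plasma cell, endothelial, adipocyte, skeletal muscle, squamous, invasion and proteolysis, hypoxia and glycolysis, TGF-beta and BMP, interferon and antigen presentation, ribosomal protein, oxidative phosphorylation, red blood cell, tissue handling, lung epithelium and anchor genes. Genes were named by rule: the 25 with the largest standard deviation of tumour means among those past the threshold, for each list up to 4 members with the smallest p and the 2 with the largest, the 10 of each sign with the largest median among those with a single sign on all arrays, and a set of anchor genes. The text names examples from these. The lists, the naming rule, the tests and most alternatives were chosen before the data were examined. The alternatives were centring, scaling and quantile normalisation of arrays, filters on missing values, slide run as a block, a robust prior, array weights, a threshold of 0.01, other list scores, and leaving out each array or tumour. Chosen after seeing the data were dye orientation as a covariate or as centring groups, dim probes left out, top values kept, single slide runs, random pairs of lists, and other definitions of the array median. Dim probes were those with over 10% of values equal, at the 3 decimals deposited, to the log2 of a ratio of whole numbers up to 10. Centring on each array's median over all measured probes followed the wording fixed in advance, and it was kept after the counts under it and under medians of the tested probes and of the probes on all arrays had been seen.

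The fits were tested on simulated data with the real probes' error, dye effect and gaps, in which 200 of 9407 probes were changed in 5 of 21 tumours. The test recovered 0% of 2-fold, 19.4% of 4-fold and 45.5% of 8-fold changes with 0 false calls, and 1.49%, 41.8% and 69.7% with dye orientation as a covariate and 4 false calls. The orientation of 42 of 42 simulated arrays was recovered. The simulated tumours shared a single profile apart from the changed probes, so this cannot show how well orientation is recovered in tumours with unlike profiles. A simulated list with a shared factor was called in 10 of 10 families with 20 random lists each, for variation and for joint movement. Of 200 random lists, 9 had an unadjusted p below 0.05 for variation and 14 for joint movement, and 0 and 3 were called after adjustment. The simulated tests thus missed most changes of each size, 8-fold included, and with the covariate most changes of 4-fold or less. Software was R 4.3.3 with limma 3.58.1, statmod 1.5.0 and mclust 6.1.1, and Python 3.11.15 with matplotlib 3.10.9.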

Results

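The samples were 42 two-colour oligonucleotide arrays carrying RNA from 21 mouse mammary tumours, with 2 arrays for each tumour. The tumours descended from neoplasms of mice that expressed a c-Myc transgene from the promoter of Wap, a milk protein gene. Serial selection in living mice had produced lines of glandular growth, of solid or comedo growth without or with lung metastases, and of spindle-cell (mesenchymal) growth. The labels name the tumour on each array but not its line, so the question the design poses, how gene expression differs between these phenotypes, could not be put to a test here. The comparisons below are between the 21 tumours, each known by its number. The p-values of limma's tests measure the error between 2 hybridisations of a tumour RNA, not the spread between animals. Those of list tests come from random draws of genes, and those of relations between list scores from permuted tumours. An array gave between 8600 and 21328 measured probes of 22800, with a median of 17478.5, and the small number of arrays per tumour limits the precision of each value. Tumour 656 is the lowest or highest tumour for several genes below. Its 2 arrays correlated at 0.074 over probes before they were turned for the dye swap, so they did not agree once turned.

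Each array set tumour RNA against a common reference RNA pool. Levels of named genes are log2 ratios after subtraction of the array's own median, which ranged from -1 to 1.38 over arrays after turning. The overall sign was set so that the median of Myc, the transgene of the design, was positive, which takes positive values as tumour over reference. The side of Myc is thus a choice and no evidence for the direction. The labels do not settle it either, so every sign below is open to being turned as a whole. A range written from tumour to tumour gives the lowest and highest tumour mean among the tumours with a value. These were 21 for most named genes but 20 for Col3a1 and 19 for Tgfbi. The standard error is that of a mean over 2 arrays. A tumour mean with a value on only 1 array has a larger error than the one printed.

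Genes of connective tissue, epithelium and milk were among those that differed between tumours. Vim, the intermediate filament of mesenchymal cells, ranged from -4.82 in tumour 656 to 1.23 in tumour 646 (standard error 0.45, n = 2 arrays, adjusted p = 8.0e-11). Epcam, an epithelial adhesion molecule, ran the other way, from -2.63 in tumour 646 to 3.53 in tumour 656 (standard error 0.48, adjusted p = 1.9e-08). The milk protein gene Csn2 ranged from -1.12 in tumour 646 to 7.46 in tumour 663 (standard error 0.64, adjusted p = 1.4e-06), and Myc from -0.73 in tumour 644 to 3.52 in tumour 667 (standard error 0.52, adjusted p = 2.4e-05). In limma's moderated F test with Benjamini-Hochberg adjustment, 1804 of 9407 tested probes (19.2%) differed between tumours at an adjusted p of 0.05, 1561 of them over a range of at least 4-fold, and 3043 probes had an unadjusted p below that threshold. Hybridisation error widens such a range, as the median standard deviation of an array within its tumour was 0.913. The 4-fold count is therefore no measure of the size of tumour differences alone. With the probes of a gene averaged, 1445 of 7629 genes differed. With slide run, read from the running numbers in the titles and not named as a batch by the labels, as a block, 710 probes differed, 679 of them among the 1804. Only 4 tumours had arrays in different slide runs, so run and tumour were largely confounded in that fit. Its lower count is no measure of a part due to slide run. With each array centred on its median, 1708 differed, of which 1137 were among the 1804.

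**Figure D1:**
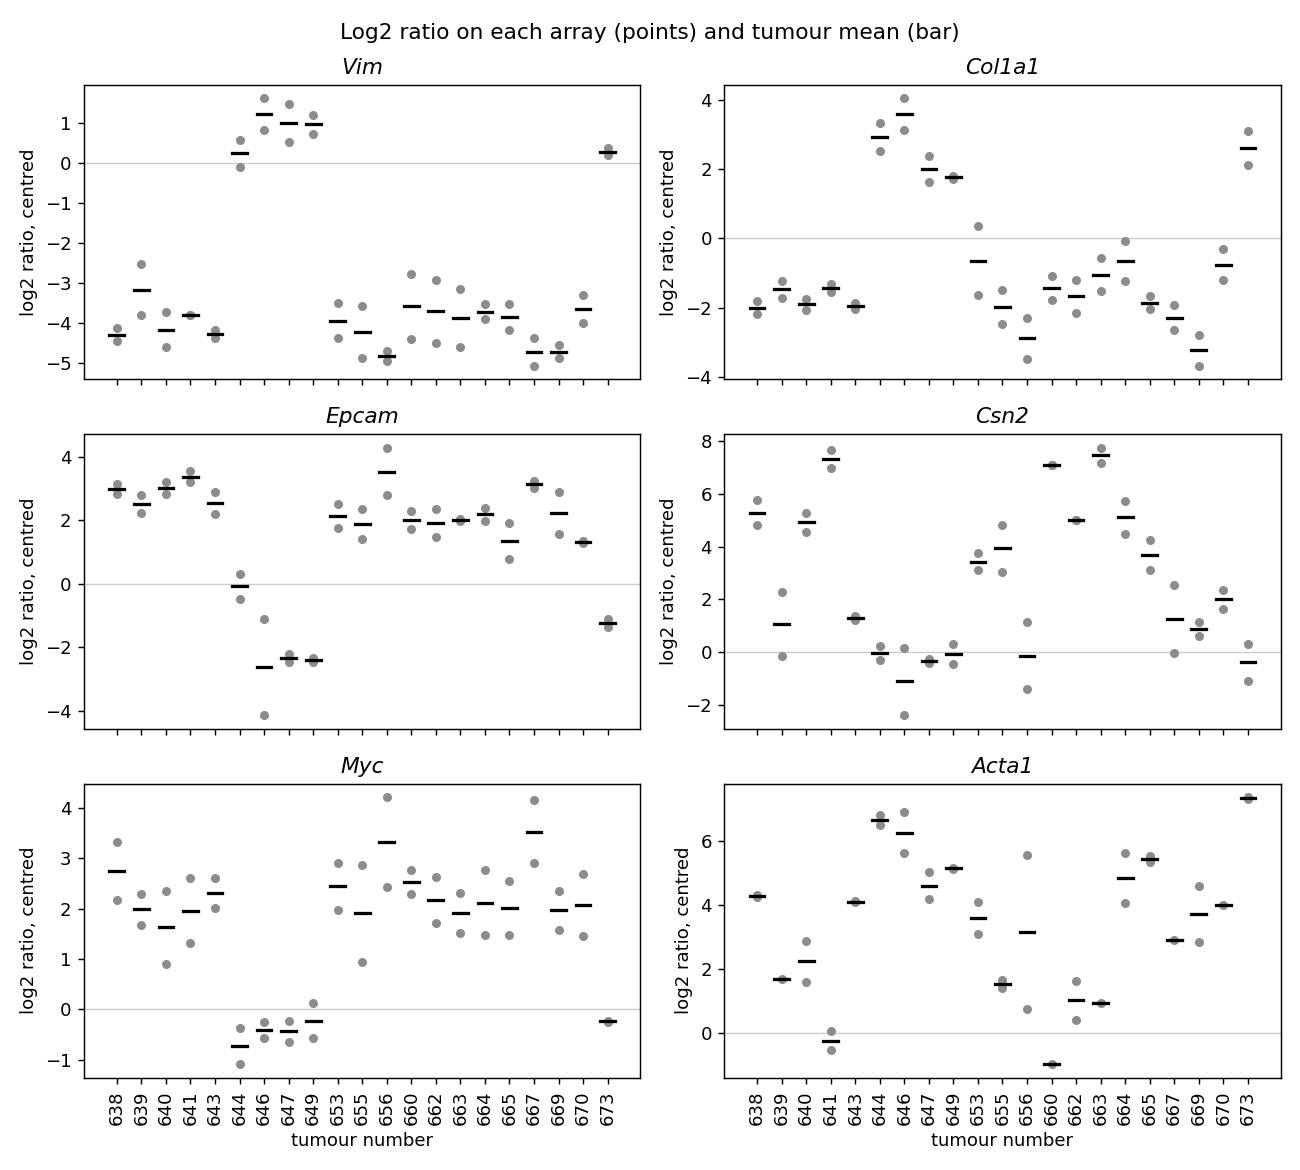
Log2 ratio after centring (vertical axis) of Vim, Col1a1, Epcam, Csn2, Myc and Acta1 in the 21 tumours (horizontal axis), with points for the arrays that had a value and a bar for the tumour mean. Vim reached 1.23 in tumour 646 and Epcam was lowest there at -2.63.

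The 25 most variable genes with a difference between tumours included the matrix list genes Col3a1, Col6a1 and Fbln2 and the milk list genes Csn2 and Csn3. The fibrillar collagen Col3a1 ranged from -10.41 in tumour 667 to 2.28 in tumour 646, Col6a1 from -6.25 in tumour 669 to 2.30 in tumour 646, and Fbln2, a fibulin of elastic fibres, from -5.92 in tumour 663 to 2.16 in tumour 646, all with adjusted p of 4.2e-04 or less. Fn1, the adhesive glycoprotein fibronectin, ranged from -5.48 in tumour 667 to 2.69 in tumour 647 by the probe with the smaller p (adjusted p = 1.0e-09). With its 2 probes averaged the range was smaller, from -4.15 to 1.72 in the same tumours. S100a4, a calcium-binding protein of motile cells, ranged from -8.42 in tumour 669 to 1.78 in tumour 649 (standard error 0.97, adjusted p = 3.3e-04). Car6, a secreted carbonic anhydrase, reached 10.51 in tumour 656 against a median of 2.19 (standard error 1.09, adjusted p = 1.1e-04). Lpo, the lactoperoxidase of milk and saliva, reached 9.07 in tumour 667 against a median of 1.47, and Mucl2, a mucin-like gene, reached 8.36 in the same tumour against 0.54. Lcn2, a siderophore-binding lipocalin, had a median of 4.49 and was lowest at -1.47 in tumour 649 (adjusted p = 7.8e-07). Dio1, a thyroid hormone deiodinase, ranged from -3.79 in tumour 664 to 8.86 in tumour 656 (standard error 0.52, adjusted p = 4.7e-08). The other 15 were Acss1, Cyp2f2, Tgfbi, Vmn1r30, Csn2, Csn3, Wnt7b, Col18a1, Col7a1, Tesc, C1qc, Loxl3, Acta1, Olfr29-ps1 and Sema7a, with adjusted p between 1.4e-06 (Csn2) and 0.0336 (Csn3).

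Of the epithelial genes, 8 of 16 measured differed between tumours, and 10 when adjusted over the list alone. Spint2, a membrane protease inhibitor of epithelia, ranged from -3.35 in tumour 649 to 3.27 in tumour 667, and Grhl2, a transcription factor of epithelial junctions, from -0.15 in tumour 665 to 4.42 in tumour 667. Perp (adjusted p = 1.7e-05) and Krt8 (0.00696) no longer passed once arrays were centred, at 0.197 and 0.196. For Perp the range went from 2.96 to 2.19 and the standard error from 0.30 to 0.50, and for Krt8 from 2.50 to 2.23 and from 0.35 to 0.42, so the calls ended with a larger error as well as a smaller range. Cldn4 (0.721) and Rab25 (0.65) did not pass the test. Of the mesenchymal genes, 11 of 16 differed, 13 over the list alone. Lgals1, a galectin abundant in mesenchyme, ranged from -4.98 in tumour 667 to 1.29 in tumour 646 (standard error 0.47), and Sparc, a matrix-binding glycoprotein, from -2.85 in tumour 669 to 2.52 in tumour 646 (standard error 0.45). Snai2 (adjusted p = 0.794) and Cald1 (0.485) did not pass.

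Of the matrix genes 14 of 15 differed, 15 over the list alone, the highest share among the 21 lists with a list test. Col1a1, the main chain of collagen I, ranged from -3.23 in tumour 669 to 3.58 in tumour 646 (standard error 0.45, adjusted p = 4.7e-09), Col1a2 from -4.57 in tumour 656 to 2.54 in tumour 646, and Bgn, the proteoglycan biglycan, from -3.93 in tumour 667 to 1.78 in tumour 646. Eln, which encodes elastin, had an adjusted p of 0.109 over all genes, 0.0366 with centred arrays and 0.0492 with dye orientation as a covariate, a setting chosen after seeing the data. In the invasion and proteolysis list 10 of 15 genes differed, 11 over the list alone, among them the membrane metalloproteinase Mmp14 (-3.47 in tumour 656 to 2.77 in tumour 646) and the metalloproteinase inhibitor Timp1 (-4.48 to 2.48 in the same tumours). In the TGF-beta and BMP list 8 of 15 differed, 10 over the list alone, among them the receptor Tgfbr2 (-4.03 in tumour 664 to 3.20 in tumour 646, standard error 0.70) and the induced matrix protein Tgfbi (-3.39 in tumour 663 to 6.03 in tumour 649, standard error 0.80).

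Set against 10000 random lists matched on hybridisation error, these 5 lists varied more between tumours, with one-sided permutation p values adjusted over 21 lists of 8.4e-04 (epithelial), 7.0e-04 (mesenchymal), 7.0e-04 (matrix), 0.0036 (invasion) and 0.0147 (TGF-beta). The value for the mesenchymal and matrix lists is the smallest that these random lists gave. The median standard deviation of tumour means was 1.92 for matrix genes against 0.80 for random lists. Members moved together beyond random lists for matrix (mean pairwise correlation 0.807 against 0.220, adjusted p = 4.2e-04), mesenchymal (0.470 against 0.209, 7.0e-04), invasion (0.403 against 0.237, 0.0268) and TGF-beta genes (0.395 against 0.242, 0.0439, and 0.0514 against unmatched lists). Epithelial genes did not pass that test as deposited (0.355 against 0.221, 0.0602) but did with centred arrays (0.00856), after quantile normalisation (0.0028) and with slide run removed (0.00783). With dim probes left out, a setting chosen after seeing the data, the invasion (0.0822) and TGF-beta (0.16) lists no longer passed it.

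**Figure D2:**
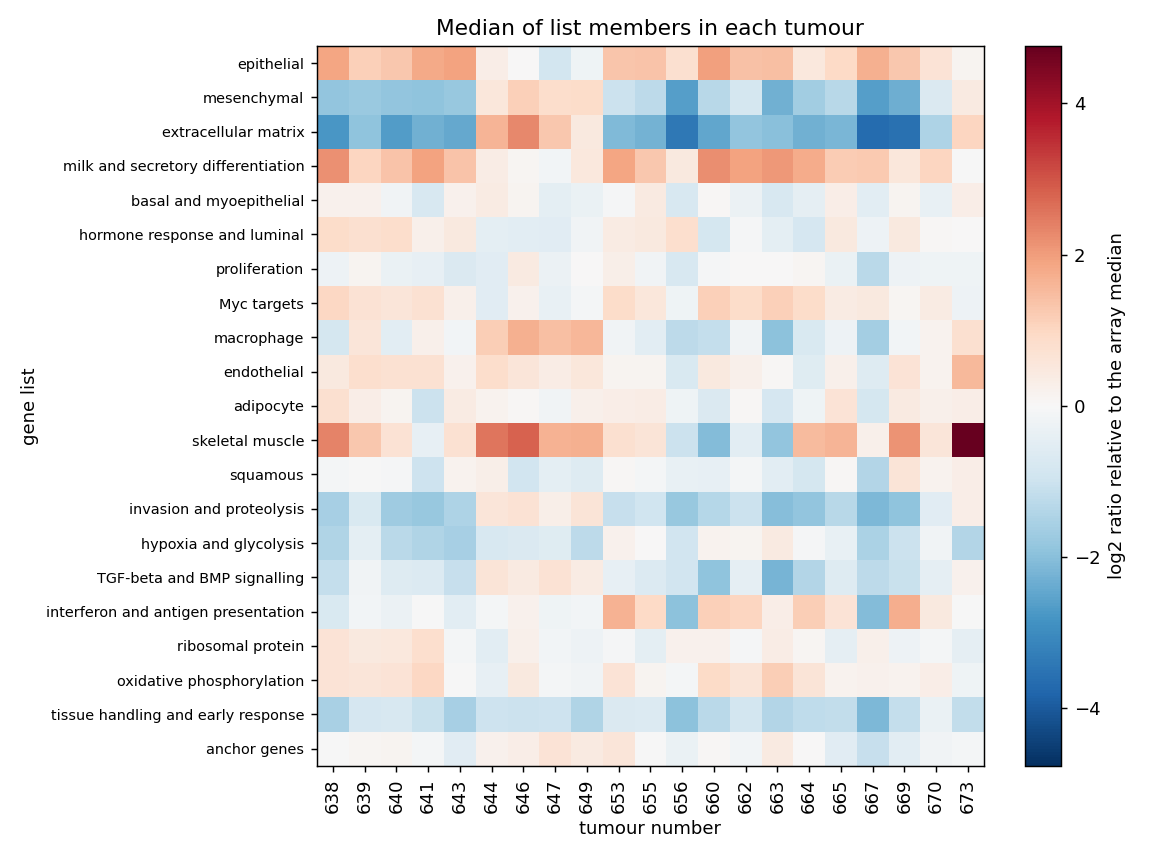
Median over list members of the log2 ratio relative to the array median (colour) for each of 21 tested lists (vertical axis) in each of 21 tumours (horizontal axis). The extracellular matrix median ranged from -3.68 in tumour 667 to 2.28 in tumour 646 and the skeletal muscle median from -2.06 in tumour 660, where 2 of 5 genes had a value, to 4.76 in tumour 673.

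Beside Csn2, a further casein gene differed between tumours. Csn3 ranged from -1.35 in tumour 647 to 9.05 in tumour 638 (standard error 1.02, adjusted p = 0.0313), and Mfge8, a milk fat globule protein, from -1.04 in tumour 669 to 2.22 in tumour 660 (0.0209). In the milk and secretory list 4 of 7 measured genes differed, 5 over the list alone, and the list neither varied more than random lists (adjusted p = 0.186, and 0.0208 by F statistic in place of standard deviation) nor moved together as deposited (0.201). Its joint movement passed with centred arrays (0.0148), after quantile normalisation (0.0207) and with slide run removed (0.0381). Of the basal and myoepithelial genes 2 of 8 differed, 3 over the list alone. Acta2, the smooth muscle actin of myoepithelium and fibroblasts, ranged from -4.42 in tumour 656 to 0.90 in tumour 646 (standard error 0.34, adjusted p = 1.2e-05), and the integrin Itgb4 from -1.17 in tumour 664 to 4.02 in tumour 649 (3.7e-04). The basal list passed neither test (0.117 and 0.35). Of the hormone response and luminal genes 2 of 9 differed, 3 over the list alone: Ccnd1, a cyclin of the G1 phase, ranged from -2.08 in tumour 656 to 2.04 in tumour 646 (adjusted p = 9.4e-06), and Xbp1, a transcription factor of secretory cells, from -0.88 in tumour 673 to 2.71 in tumour 641 (7.7e-06). Esr1, the oestrogen receptor, did not pass (0.847). The list moved together (adjusted p = 0.0168, and 0.142 with dim probes left out) but did not vary more than random lists (0.188, and 0.0403 by F statistic). The squamous genes, 0 of 7 differing in limma's test with 0 over the list alone and 2 at an unadjusted p below 0.05, moved together (0.0147) without more variation (0.117, and 0.0292 against unmatched random lists). With dye orientation as a covariate, where 45% of all genes differed, 4 of 8 basal, 6 of 9 hormone response and 3 of 7 squamous genes differed, among the last Sfn, a 14-3-3 protein of keratinocytes (adjusted p = 0.00749).

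Of the proliferation genes 4 of 21 (19%) differed, and 4 over the list alone, beside 18.9% of all genes. Those named by the rule included Aurka, a mitotic kinase, ranging from -1.36 in tumour 656 to 2.95 in tumour 653 (standard error 0.31, adjusted p = 4.1e-05) and the mitotic motor Kif11 from -1.59 in tumour 643 to 1.17 in tumour 663 (0.00815). Mki67 (0.394) and Mcm7 (0.898) did not pass, nor did the list for variation (0.799). Joint movement of proliferation genes missed the threshold as deposited (0.06) and passed it with centred arrays (2.3e-04), after quantile normalisation (2.6e-04) and with slide run removed (5.2e-04). Of the 21 genes 10 differed with dye orientation as a covariate, near the 45% of all genes. Of the Myc target genes 12 of 21 differed, 16 over the list alone and 8 with centred arrays. Tfrc, the transferrin receptor, ranged from -3.19 in tumour 644 to 2.74 in tumour 667 (standard error 0.50, adjusted p = 1.4e-06), and Shmt1, an enzyme of one-carbon metabolism, from -1.50 in tumour 647 to 3.21 in tumour 667 (5.3e-05). Myc targets moved together (mean correlation 0.538 against 0.228, adjusted p = 4.2e-04) without more variation than random lists (0.207), though by F statistic they passed for variation (0.0309). Among the anchor genes, chosen as drivers of mammary cancer, 5 of 9 measured differed, 6 over the list alone, including Myc and Ccnd1, and that list passed neither test (0.151 and 0.992).

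Most calls among ribosomal and mitochondrial genes were lost when arrays were centred. Of 16 ribosomal protein genes 11 differed as deposited, 13 over the list alone, but 1 did with each array centred on its median, and of 20 oxidative phosphorylation genes 5 differed, 6 over the list alone, and 2 with centred arrays. With dye orientation as a covariate 14 and 13 differed, beside 45% of all genes. For Rpl19 the adjusted p was 0.00391 as deposited and 0.571 centred, with a range of 2.36 and 1.85 and a standard error of 0.31 and 0.44. For Cox6c it was 0.00438 and 0.733, with a range of 2.12 and 1.66 and a standard error of 0.27 and 0.44, so a larger error had a part in these losses. Rpl32 was the ribosomal gene that stayed past the threshold, at 5.3e-04, with -1.50 in tumour 649 and 3.41 in tumour 656. Both lists moved together (mean correlations 0.629 and 0.580, adjusted p = 4.2e-04 for each), also with centred arrays (0.496 against 0.152 and 0.537 against 0.155, 2.3e-04 for each). Neither varied more than random lists (0.316 and 0.846). Hypoxia and glycolysis genes differed for 5 of 12, 6 over the list alone and 8 with centred arrays. Bnip3, a hypoxia-induced mitophagy receptor, ranged from -4.36 in tumour 667 to 0.48 in tumour 663 (standard error 0.48, adjusted p = 7.7e-05), and the list passed neither test as deposited (0.217 and 0.321). With centred arrays it passed for variation (0.0415). Its joint movement passed with centred arrays (2.3e-04) and after quantile normalisation (2.6e-04) but not with slide run removed (0.127).

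Genes of other cell types in the tumours differed unevenly. Macrophage genes differed for 11 of 14, 12 over the list alone. Msr1, a scavenger receptor, ranged from -7.13 in tumour 656 to 1.63 in tumour 649 (standard error 0.54, adjusted p = 1.8e-07), the complement gene C1qc from -2.54 in tumour 663 to 5.56 in tumour 649, and Fcer1g, an Fc receptor chain, from -4.71 in tumour 667 to 1.68 in tumour 646. The macrophage list varied more (adjusted p = 7.0e-04) and moved together (0.736 against 0.222, 4.2e-04). Its median was highest in tumours 646 (1.70), 649 (1.57), 647 (1.43), 644 (1.16) and 673 (0.77), which also had the 5 highest matrix medians. Interferon and antigen presentation genes differed for 10 of 18, 11 over the list alone, with the MHC class II chaperone Cd74 between -3.41 in tumour 660 and 2.28 in tumour 644 and the interferon-induced Oas1a between -1.68 in tumour 656 and 2.04 in tumour 660, and that list passed both tests (8.4e-04 and 0.0193). Skeletal muscle genes differed for 2 of 5, 3 over the list alone: Acta1, the skeletal actin, ranged from -1 in tumour 660 to 7.35 in tumour 673 (standard error 0.70, adjusted p = 8.4e-04), while Mylpf (0.102, and 0.0026 with dye orientation as a covariate) and Ckm (0.235) did not pass as deposited, and the list passed both tests (0.0021 and 0.0156). Adipocyte genes differed for 3 of 7, 3 over the list alone, with the desaturase Scd1 between -2.41 in tumour 641 and 2.80 in tumour 664 (7.8e-06). The adipocyte list varied more than random lists (0.0359), but not with centred arrays (0.0725), after quantile normalisation (0.19) or by F statistic (0.139), and did not move together (0.169, and 0.0429 with slide run removed). Endothelial genes differed for 0 of 7, 0 over the list alone and 2 at an unadjusted p below 0.05, and moved together (0.006) without more variation (0.773). With dye orientation as a covariate 4 of the 7 differed, beside 45% of all genes, among them Tie1 (0.0167) and Emcn (0.019).

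T and NK cell genes differed for 0 of 4, 0 over the list alone and 1 at an unadjusted p below 0.05, with Cd8a at an adjusted p of 0.667, and the single measured B cell gene, Blnk, ranged from -2.60 in tumour 644 to 1.98 in tumour 667 (0.019). Of the red blood cell genes 1 of 2 differed, 1 over the list alone: Hba-a1, an alpha globin, was positive in every tumour, from 1.06 in tumour 662 to 8.63 in tumour 673 (standard error 0.49, adjusted p = 5.5e-05). The lung epithelium genes, a marker of lung tissue, differed for 0 of 2, 0 over the list alone and 0 at an unadjusted p below 0.05. These 4 lists had too few measured genes for a list test. Early response genes of tissue handling differed for 0 of 10, 0 over the list alone, 2 at an unadjusted p below 0.05 and 2 with centred arrays, with Egr1 at an adjusted p of 0.0587 and Fos at 0.865, and the list passed neither test (0.773 and 0.201). With dye orientation as a covariate 5 of the 10 differed, beside 45% of all genes, among them Jun (0.00186), Hspa1a (0.0166), Fos (0.0174) and Egr1 (0.0267).

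A small set of probes lay on the same side of the reference in every tumour. With the same sign on all 42 arrays and a median of at least 1 in size, 38 probes were positive and 43 negative, and 8 and 5 of them had a gene name. Among all 9407 tested probes 7984 had 1 gene, so this set was mostly of unnamed probes, and what those measure was not analysed. On the positive side, Hba-a1 had a median of 3.42 (tumour means from 1.06 to 8.63), the brown fat uncoupling protein Ucp1 1.86 (0.72 to 2.66), Dbi, an acyl-CoA binding protein, 1.85 (0.97 to 2.85), the transcription factor Nfib 1.67 (0.71 to 2.30) and the actin crosslinker Actn4 1.39 (0.46 to 2.29). On the negative side were the lysosomal protease Ctsl at -1.88 (-3.93 to -0.54), Ccn1, a secreted matricellular protein, at -2 (-2.72 to -0.25), the ribosomal stalk gene Rplp1 at -1.41 (-2.22 to -0.60), a ferritin pseudogene, Fth-ps3, at -1.64 (-2.50 in tumour 669 to 0.07 in tumour 646) and Glo1, a glyoxalase, at -1.15 (-1.98 to -0.07). Of these 10 genes, Hba-a1, Dbi, Ctsl, Ccn1 and Fth-ps3 also differed between tumours as deposited, and Hba-a1 and Fth-ps3 with centred arrays. No test was made against the single reference pool, and with the sign turned the counts become 43 positive and 38 negative. With centred arrays there were 45 positive and 34 negative probes.

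Pairs of tumours differed by as little as 0 and as much as 1791 probes at a log2 difference of at least 1. The median over 210 pairs was 170.5 probes. As deposited, tumours 663 and 669 differed most, with 1791 probes, but with centred arrays this pair had 675 probes and tumours 646 and 667 differed most, with 1233. In limma's test as deposited, 23 pairs differed in 0 probes. Such pairs had between 23 probes (tumours 655 and 665) and 600 probes (655 and 664) of that size at an unadjusted p below 0.05. The median share of a probe's variance that lay between tumours, the intraclass correlation, was 0.206 (jackknife standard error 0.163 over arrays left out in turn) and 0.647 in the 1804 probes. With slide run as a block the median pair differed in 17 probes. Run effects in that fit rest on the 4 tumours with arrays in different slide runs. Contrasts between tumours of unlike runs are therefore less precise, and the fall does not show how much slide run accounts for.

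The array most like a given array was seldom the other array of its tumour. By Pearson correlation over probes, 1 of 42 arrays was closest to its tumour partner (one-sided permutation p = 0.6), and 39 were closest to an array of the same dye orientation. With each probe centred within its dye orientation, a setting chosen after seeing the data, 15 arrays were closest to their partner (permutation p = 1e-05, the smallest that 100000 permutations can give) and 28 to an array of the same slide run. With dye orientation as a covariate, also chosen after seeing the data, 4132 probes differed between tumours, and all 1804 were among them.

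**Figure D3:**
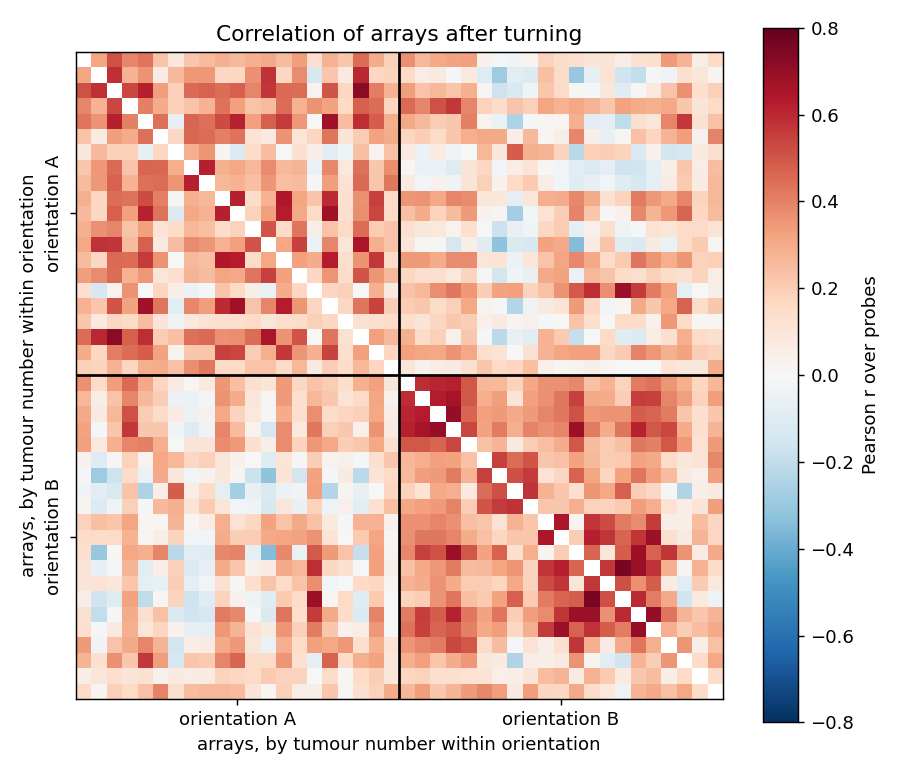
Pearson correlation over probes (colour) between the 42 arrays after turning, ordered by dye orientation and then by tumour number on both axes, with 21 arrays per orientation. Of the arrays, 39 had their closest array within their own orientation block.

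Relations between the scores of 12 pairs of lists were computed, and 8 passed a Benjamini-Hochberg adjusted p of 0.05 over the 12. The permutations treated tumours as independent, which could not be checked because the labels do not name their lines. Where tumours of a line are alike, these p-values are too small. Mesenchymal and matrix scores each lay in 2 components of 16 and 5 tumours, so for the 7 pairs holding either, correlations were taken within the 16 tumours and the component of 5 was too small for a value. Slide runs 1 and 2 held 4 and 5 whole tumours, too few for a value, and within-run values are therefore from the 8 tumours of slide run 3, with exact permutation p. Of these, 5 belonged to the component of 16, too few for a value of that component within the run. For 3 of the 7 pairs a value was had over all 8 tumours, which span both components and so measure another quantity: r = 0.99 for mesenchymal with invasion (exact permutation p = 5.0e-05), 0.96 for mesenchymal with TGF-beta (3.2e-04) and -0.85 for epithelial with mesenchymal scores (0.0121). Epithelial and milk scores correlated over 21 tumours (r = 0.76, permutation p = 7.0e-05, adjusted p = 8.4e-04, rho = 0.68, p = 0.00106), with r of 0.77 without the 2 tumours farthest from the median epithelial score and 0.80 within the run (exact permutation p = 0.0121). Mesenchymal and matrix scores correlated over 16 tumours (r = 0.79, permutation p = 4.0e-04, adjusted p = 0.0016, rho = 0.74, p = 0.00179, 0.69 without 2 tumours). Mesenchymal and invasion scores did so too (r = 0.79, permutation p = 3.6e-04, adjusted p = 0.0016, rho = 0.79, p = 6.1e-04, 0.60 without tumours 663 and 670). Invasion scores had components of their own, of 15 and 6 tumours, and tumour 670 lay in the upper one, so these 16 tumours span both. Mesenchymal and TGF-beta scores had r = 0.67 (permutation p = 0.00423, adjusted p = 0.0127, rho = 0.65, p = 0.00721), and without tumours 663 and 670 r was 0.44, no longer past the threshold (permutation p = 0.113). Pairs of random lists of the same sizes, a comparison added after seeing the data, had median r between 0.70 and 0.89 over the same tumours, and each of the 12 relations lay below its own median. The 8 relations past the threshold, whose p is against an r of 0, exceeded between 1.7% (macrophage with matrix) and 41.2% (epithelial with milk) of 1000 random pairs, and with centred arrays the highest placed, mesenchymal with matrix, exceeded 83.7%. With centred arrays 4 relations passed, namely epithelial with milk, mesenchymal with matrix, mesenchymal with invasion, and proliferation with hypoxia genes.

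Macrophage and matrix scores correlated over 16 tumours (r = 0.62, permutation p = 0.0109, adjusted p = 0.0262, rho = 0.65, p = 0.00797, 0.66 without 2 tumours), as did endothelial and matrix scores (r = 0.56, permutation p = 0.0223, adjusted p = 0.0377, rho = 0.61, p = 0.0144). Neither passed with centred arrays (r = 0.43 and 0.44, adjusted p = 0.13 for each). With slide run removed the first passed (r = 0.59, adjusted p = 0.0373) and the second did not (r = 0.49, adjusted p = 0.0849). Without tumours 663 and 664 the endothelial r was 0.44, no longer past the threshold (permutation p = 0.114). Macrophage and T and NK cell scores had r = 0.49 over 21 tumours (permutation p = 0.0251, adjusted p = 0.0377, rho = 0.56, p = 0.00919, 0.47 without 2 tumours) and 0.17 within the run (exact permutation p = 0.686). The T and NK score holds 4 genes, of which Cd8a (-0.07), Cd3g (-0.35) and Prf1 (-0.58) had a negative intraclass correlation. It thus holds mostly hybridisation error, and no relation between the cell types is read from it. Epithelial and basal scores (r = 0.50, permutation p = 0.0204, adjusted p = 0.0377, rho = 0.54, p = 0.0134) had a similar r in fewer tumours, at 0.44 within the run (exact permutation p = 0.26) and 0.43 without tumours 643 and 667 (permutation p = 0.0619), neither past the threshold, -0.09 with centred arrays (adjusted p = 0.702) and 0.41 with slide run removed (adjusted p = 0.0849). Proliferation passed neither with Myc targets (r = 0.38, permutation p = 0.0865, adjusted p = 0.115, rho = 0.38, p = 0.0929, 0.26 without 2 tumours, 0.01 within the run) nor with hypoxia genes (r = 0.18, permutation p = 0.424, adjusted p = 0.509, rho = 0.15, p = 0.524, 0.06 without 2 tumours, 0.52 within the run). With centred arrays the relation of proliferation and hypoxia was r = 0.59 (adjusted p = 0.0118), and with slide run removed r = 0.50 (adjusted p = 0.0373).

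Epithelial and mesenchymal scores had an r near 0 in the 16 tumours (r = -0.04, permutation p = 0.887, adjusted p = 0.887, rho = 0.06, p = 0.832, -0.05 without 2 tumours), while random pairs had a median r of 0.89 and none of them lay as low. With centred arrays r was -0.57 (adjusted p = 0.052) and rho -0.64 (adjusted p = 0.0212). With slide run removed no components were found, and over all 21 tumours, which span both components of the deposited scores, r was -0.70 (adjusted p = 0.00136). Within slide run 3, over 8 tumours of both components, r was -0.85 (adjusted p = 0.0242). Epithelial and matrix scores did not pass either (r = 0.17, permutation p = 0.535, adjusted p = 0.584, rho = 0.14, p = 0.602, 0.26 without 2 tumours).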

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

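The settings with dye orientation as a covariate or as centring groups, dim probes left out and single slide runs were chosen after seeing the data; the others were planned. The 1804 probes differing between tumours became 598 with no filter on missing values, 710 with slide run as a block, 2739 with array weights, 4132 with dye orientation as a covariate, 877 at a threshold of 0.01, and 0, 0 and 208 within slide runs 1, 2 and 3 alone by limma, where fewer tumours entered and 1151, 585 and 1451 probes had an unadjusted p below 0.05. The 1561 by 4-fold became 683 with the block and 3490 with orientation. The median pair count of 170.5 became 103.5 with scaled arrays, 97 after quantile normalisation, 17 with the block and 492 with orientation, and the variance share of 0.206 became 0.381 with orientation. Probes on a single side numbered 246 by the sign of tumour means in place of 81, and 15 arrays in place of 1 were closest to their partner with probes centred within orientation. Lists moving together fell from 13 to 7 with dim probes left out, where 3 of the 13 had too few genes for a test, and rose to 17 with centred arrays, after quantile normalisation and with slide run removed, with epithelial, milk and proliferation lists gained each time. Relations past the threshold fell from 8 to 5 with first principal components, 3 with medians of members, 4 with centred arrays and 4 within slide run 3, where 3 of the 4 were taken over tumours of both components. For all of these the cause was not tested beyond the smaller number of tumours or genes named. Leaving out an array or a tumour gave 1448 (without the second array of tumour 641) to 2867 probes (without the second array of tumour 660), and 1292 to 2629 by 4-fold without the same arrays, 121.5 to 226 for the median pair, 0.178 to 0.313 for the variance share, 80 to 100 on a single side, 8 to 9 lists for variation, 11 to 15 for joint movement and 3 (without tumour 663) to 9 relations (without tumour 667), with 4 without tumour 639 or 643 and 5 without 656 or 664. Signs reversed for epithelial against matrix scores, at -0.23 with centred arrays and -0.36 with slide run removed, for epithelial against basal at -0.09 with centred arrays, and for mesenchymal against TGF-beta at -0.78 with slide run removed, over 6 tumours (adjusted p = 0.0849), where the other component of 15 had 0.73 (adjusted p = 0.00585). Proliferation against hypoxia fell to 0.00 with medians. Other components arose in some settings: with first principal components this pair had -0.37 and -0.02 over 11 and 10 tumours, and with medians, over 11 and 7, epithelial scores had -0.45 and -0.72 with matrix, -0.32 and -0.06 with basal and 0.43 and -0.03 with milk scores, none past the threshold. Epithelial against mesenchymal scores ranged from -0.22 to 0.12 as a tumour was left out, crossing 0 without 638 (0.01), 665 (0.02), 667 or 670 (0.08), and the cause was not tested. Of the named list genes, 21 calls were lost and 0 gained with slide run as a block, 14 were lost and 6 gained with centred arrays, and 0 were lost and 20 gained with dye orientation as a covariate. No paired analysis was possible because replicate numbers only name the 2 arrays of a tumour in accession order. The 9 lists with more variation became 7 to 11 under the other settings tried. Signal over background was not used here.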

Other observations

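The comparisons of slide run with matrix, mesenchymal and invasion scores and of tissue genes with the direction were chosen after the results were seen, and the others before. With positive values taken as tumour over reference, Myc was lowest in the 5 tumours with the highest matrix medians; with the overall sign turned, these would have the lowest matrix medians and the highest Myc. The matrix median was 2.28 in tumour 646, 1.60 in 644, 1.27 in 647, 1.01 in 673 and 0.47 in 649, and Myc in the same tumours was -0.41, -0.73, -0.43, -0.24 and -0.23. In the other 16 tumours the matrix median ran from -3.68 in tumour 667 to -1.47 in tumour 670, and Myc from 1.63 in tumour 640 to 3.52 in tumour 667. Epcam was also lowest in these 5, though not in the order of Myc, at -2.63 in tumour 646, -0.08 in 644, -2.34 in 647, -1.23 in 673 and -2.39 in 649, with 1.32 in tumour 670 as the lowest of the other 16. The epithelial keratins were divided. Krt8 was 2.71, 2.29, 2.63, 2.26 and 2.99 in the same order, with 2.46 in tumour 643 as the highest of the others. Tumours 644 and 673 thus lay within the spread of the others, and centred Krt8 did not pass limma's test (adjusted p = 0.196). Krt18 was low, at 0, -1.49, -1.08, -0.98 and -0.42. Elsewhere it ran from 0.16 in tumour 643 to 1.03 in tumour 638, apart from -2.96 in tumour 656 and -0.66 in tumour 664. Vim was between 0.24 in tumour 644 and 1.23 in tumour 646 in these 5 and at most -3.17, in tumour 639, elsewhere. Some markers of other cell types stood apart in these 5 and others did not. The macrophage median was 1.70 in tumour 646, 1.16 in 644, 1.43 in 647, 0.77 in 673 and 1.57 in 649, and at most 0.57, in tumour 639, elsewhere. Hba-a1 was 5.14, 5.76, 4.79, 8.63 and 4.82 in the same tumours, and at most 4.76, in tumour 656, elsewhere. With a standard error of 0.49, Hba-a1 thus did not set tumours 647 and 649 apart from tumour 656. Acta1 was 6.66 in tumour 644, 6.27 in 646, 4.61 in 647, 5.15 in 649 and 7.35 in 673, with 5.44 in tumour 665 as the highest of the others. The B cell gene Blnk was low, at -2.11 in tumour 646, -2.60 in 644, -1.64 in 647, -1.72 in 673 and -1.67 in 649, but also at -2.43 in 664. In the same order, medians within the spread of the other tumours were those of T and NK cell genes (-0.24, -0.26, -0.22, 0.40 and -0.28) and adipocyte genes (0.07, 0.18, -0.18, 0.33 and 0.25). Endothelial medians were 0.57, 0.83, 0.34, 1.54 and 0.55, with 0.79 in tumour 639. Among the pairs formed by these 5, tumours 644 and 649 differed in 2 probes and every other pair in 0, where the median over all 210 pairs was 170.5. No biological explanation was tested, since the labels give no line for a tumour, and the tumours were singled out after their values were seen.

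Scores of ribosomal and oxidative phosphorylation genes each lay in components of 13 and 8 tumours. The upper ribosomal component held tumours 638, 639, 640, 641, 643, 656, 667 and 669, and the upper oxidative one held 653 in place of 656. The ribosomal median over centred arrays had a small range, from -0.49 in tumour 644 to 0.81 in tumour 641, and the oxidative one from -0.38 in tumour 644 to 1.17 in tumour 663. The components came from scores without centring, and the centred medians did not follow them throughout. Tumours 643 (-0.11) and 669 (-0.26) were in the upper ribosomal component, and tumour 663 was in the lower oxidative one. The alpha globin Hba-a1 and the skeletal actin Acta1 were both highest in tumour 673, at 8.63 and 7.35.

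Differences between tumours were set against other pairings of the arrays. Of 100 pairings of arrays of opposite orientation, the labelled one included, only 1, the labelled one itself, gave as many differing probes, with 1804 against at most 2 in the others, so chance pairing can be excluded. The pairings did not keep arrays within slide runs.

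Mesenchymal, matrix and invasion scores fell into separate components. Matrix and mesenchymal scores gave 16 and 5 tumours, and invasion gave 15 and 6, with tumour 670 added to the 5. A dye effect is argued against, because the arrays of each orientation alone put 21 of 21 tumours in the same matrix component. Whether a tumour was wrongly turned cannot be decided from this agreement. The arrays of a tumour were always turned as an opposed pair, so a wrong turn would reverse its score in each orientation alike. After turning, 28 probes with values on at least 30 arrays had a median of at least 5 in size. Of their 1004 array values 994 lay on the side of the probe's median, and on each of 42 arrays most did. For these probes, picked from the turned values, this argues against a wrongly turned tumour. Slide run as the whole source is argued against for the matrix score as well, because the tumours with both arrays in slide run 3 spanned 92.3% of its full range. With slide run removed, matrix scores still gave components of 16 and 5 tumours. Mesenchymal and invasion scores then gave no components. As deposited, mesenchymal scores in slide run 3 were at least 0.87 in tumours 647, 649 and 673. They were at most 0.28, in tumour 670, in the other tumours with both arrays in that run. In slide run 1 the score was 1.32 in tumour 644 and at most -0.2, in tumour 639, in the other whole tumours. This argues against slide run as the whole source for mesenchymal scores. Invasion scores lay closer in slide run 3, at 0.43 in tumour 670 and 0.26 in 643, and slide run stays open for their separation. A difference in tumour line or in stromal content stays open as untested.

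Genes of milk, muscle and blood lay mostly on the positive side. Of 14 measured genes of these tissues 11, or 78.6%, had a positive median, against 43.8% of all genes. As this share restates the pattern that prompted it, it decides nothing about the direction. Probes at the top value, read as a denominator of 0 without a test of that reading, gave no decision: they overlapped between tumours 3.34 times as often as chance in orientation A and 2.85 times in orientation B, a ratio of 1.17 that fell short of the 1.2 set in advance. The direction against the reference therefore stays unsettled.

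Skeletal muscle genes differed widely between tumours, with list medians of 4.76 in tumour 673, 2.79 in 646, 2.56 in 644 and -2.06 in 660, where only 2 of the 5 genes, Acta1 and Eno3, had a value. Muscle tissue taken with the tumour may be the source: 14 further muscle genes correlated with the list over tumours at r = 0.73, at percentile 100 among random lists, whose 95th percentile was 0.34. In tumour 673 Acta1 was 7.35, Mylpf 7.23 and Ckm 4.76, the highest values of these genes, while Eno3 was 1.73 and Tnni2 1.03, and these were highest in tumours 646 (1.81) and 638 (1.66). The list genes did not all go together. Tnni2 was -1.85 in tumour 646 and -1.69 in 647, near its lowest of -1.94 in 670, while Acta1, Ckm, Mylpf and Eno3 were positive in 646 and 647. With the overall sign turned the order of the tumours turns as a whole, so which tumours had more muscle expression stays open. Expression of muscle genes by the tumour cells themselves stays open, and which of the list's genes mammary tumours also express was not analysed here.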
